A study of Homo sapiens with 33 samples.

How the data were processed

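RNA-seq was read from a deposited table of gene-level FPKM values (fragments scaled to transcript length and to the number of mapped fragments) for T47D cells, an estrogen receptor positive human breast cancer line. The series holds 33 samples of several such lines and their drug-resistant derivatives. The table used here has a column for each of 5 of them, and the other 28 samples were not analysed here. The 5 libraries are 2 of the endocrine-sensitive parental cells and 3 of a palbociclib-resistant derivative. Palbociclib inhibits the cell cycle kinases CDK4 and CDK6. Per the labels' protocols, the derivative was raised in stepwise higher doses and then kept in 1 µM palbociclib, and cells were harvested in their usual medium. The drug was thus in the medium of the resistant cells only. Nothing in the labels says whether replicates were separate cultures, so p-values measure only the spread between these libraries, which can be technical.

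Per the labels' protocols, total RNA was isolated on columns with DNase treatment and libraries were made with a TruSeq RNA kit. Per the submitters' processing notes, CASAVA, Bowtie, Cuffdiff and Cufflinks 2.2.1 were used with the hg19 build. The gene annotation, the use of strand and any scaling between libraries are not given in the sources used here. The table's name speaks of counts, but the deposited values are FPKM: they are not whole numbers, and in genes with a single annotated transcript the low values multiplied by transcript length gather at a size that differs by library, as the value of 1 fragment does. That size gave rough depths of 18600000 and 31900000 fragments for parental replicates 1 and 2. It gave 20000000, 15400000 and 11300000 for resistant replicates 1, 2 and 3. Between 20.0% and 30.9% of the low values per library lay within 20% of it, so these depths are approximate and no counting interval was derived from them.

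The tests planned for counts, with their scalings and filters, do not apply to FPKM. The plan's fallback for normalized values was used: limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(FPKM + 1), with group as the only term. Genes needed at least 1 FPKM in at least 2 libraries, a filter chosen after the unit was known. It kept 12096 of 16547 listed genes. Calls required a Benjamini-Hochberg adjusted p under 0.05. A log2 change is on the log2(FPKM + 1) scale and understates the change of genes with low values. Folds are ratios of group means in FPKM.

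A set of 28 gene lists was fixed before the data were examined and tested with camera from limma at a preset correlation of 0.01, with adjustment over the 27 lists that had tested members. Camera was repeated with an estimated correlation, and fry gave a test of each list by itself. A call lost with the estimated correlation need not reflect correlation. The interferon gamma-type response list had an estimated correlation of -0.0127, below the preset. Its unadjusted camera p still rose from 0.000140 to 0.0256 in that setting. In other lists, such as the type I interferon response (0.0771), the estimate lay above the preset. Named genes followed a rule fixed at the same time. It took the 10 highest and the 10 lowest log2 changes among called genes with separate groups and a mean of at least 5 FPKM. From each list it took up to 3 called members with the largest change and a mean of at least 1 FPKM, or the 2 members with the highest mean where none was called. A fixed set of cell cycle, receptor and interferon genes was always named. Other genes named, such as neighbours of RB1, genes at the ends of windows, markers and those of the closing paragraphs, stand outside the rule and were chosen after the data had been seen.

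The fit was tested on simulated data with 12096 genes. Of 200 genes changed by 0.5, 1 or 2 on the log2 scale, 13 lowered ones whose log2 mean was near or under the step were counted apart, and 12 of these were called. Of the other 187, 45.5%, 98.4% and 100% were called at the 3 steps, 150 in all, and 5 of the 167 calls (2.99%) were false. The simulated noise was normal, independent between genes and drawn from the spread that the fit itself estimated. It held no shift of whole libraries, and far fewer genes changed than were called in the real data. These rates thus need not hold for the real calls. Alternatives covered scaling, the filter on low values, the pseudocount, robust variance moderation, a replicate block, stricter thresholds and leaving out each library. Scaling to the total without mitochondrial genes was added after seeing the data. A left-out library kept the genes of the full fit.

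Gene order came from RefSeq on GRCh38.p14, another build than the authors', so no coordinates are given and only which genes neighbour each other was used. It placed 11832 of the tested genes. Transcript sequences and overlaps came from GENCODE. Further computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.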

Results

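Gene expression was compared between endocrine-sensitive parental T47D breast cancer cells (n = 2 libraries) and their palbociclib-resistant derivative (n = 3 libraries). The series title names interferon signalling, resistance to CDK4/6 inhibitors and immune checkpoints as its subjects. FPKM summed to 733535 and 713179 in parental replicates 1 and 2, and to 653691, 663659 and 682627 in resistant replicates 1, 2 and 3. Mitochondrially encoded transcripts made up 18.4% of the sum in parental replicate 1 and between 10.8% and 12.4% in the other 4 libraries. On the log2 scale, the parental libraries correlated across genes at r = 0.993, the resistant ones at 0.991 to 0.993, and libraries of different groups at 0.959 to 0.963.

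Resistant cells had almost no RB1 transcript, while interferon-stimulated genes and SNCG, which encodes gamma-synuclein, were higher. X-linked cancer-testis genes changed in both directions, with MAGEA3 and MAGEA6 higher and VCX2 and VCX3B lower. RB1, the retinoblastoma protein gene whose product CDK4 and CDK6 phosphorylate, stood at 15.9 ± 0.323 FPKM (SD, n = 2) in parental cells and 0.0188 ± 0.0132 (SD, n = 3) in resistant cells. SNCG rose from 5.01 ± 1.20 to 236 ± 25.6 FPKM, a 47.2-fold difference. Of 12096 genes tested, 2900 were higher and 1762 lower in resistant cells (limma, adjusted p under 0.05). Of these, 292 and 218 changed by at least 1 on the log2 scale. In each called gene the groups did not overlap, which selection by a small p-value makes likely and which is no separate support. Chance alone separates the groups in 20% of genes. Median-of-ratios scaling turned the split to 2257 higher and 2467 lower, upper quartile scaling to 2449 and 2262, and total FPKM scaling to 4145 and 1251. Without parental replicate 1 there were 1693 higher genes, and without parental replicate 2 there were 1862 higher and 911 lower.

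The CDK4/6, cyclin D and RB list had 28 tested members, of which 10 rose, 3 fell and 15 did not pass. Adjusted over the list alone, 11 rose and 3 fell. RB1 had the largest fall of the tested genes named by the rule, with a log2 change of -4.06 (SE 0.0978, limma adjusted p = 1.57e-06), and of -7.08 with a pseudocount of 0.1. The cyclin E genes, whose products activate CDK2, were higher: CCNE1 rose from 5.71 ± 0.362 to 11.8 ± 0.774 FPKM and CCNE2 from 20.5 ± 0.602 to 30.8 ± 2.17. CCND1, encoding cyclin D1, rose 1.36-fold, but its adjusted p was 0.0515 without parental replicate 2 (limma). CDKN1A, encoding the CDK inhibitor p21, rose 2.02-fold. CDKN2A, encoding p16, fell from 36.3 ± 1.23 to 20.1 ± 4.15 FPKM, with an adjusted p of 0.0513 without parental replicate 1 (limma). The drug's targets did not pass: CDK4 was at 378 ± 48.9 and 448 ± 23.1 FPKM (limma adjusted p = 0.0815) and CDK6 at 1.17 ± 0.0985 and 1.66 ± 0.314 (limma adjusted p = 0.125). CDK2 was at 58.6 ± 0.0269 and 69.1 ± 6.89 FPKM (limma adjusted p = 0.0953). CDK4 and CDK2 passed under total FPKM scaling (limma adjusted p = 0.0187 and 0.0158), also when mitochondrial genes were left out of the total (0.0147 and 0.0245), and CDK4 also without parental replicate 2 (limma adjusted p = 0.0361). MYC, at 12.3 and 12.4 FPKM, did not pass either. The list as a whole did not stand apart from other genes (camera adjusted p = 0.214).

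**Figure D1:**
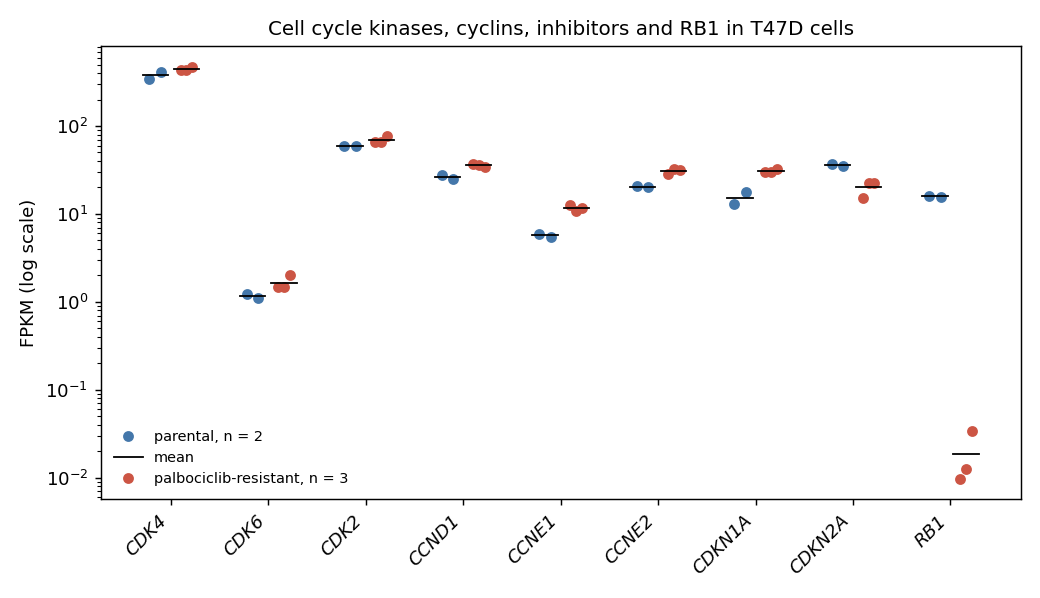
FPKM per library on a log axis for cell cycle genes in parental (n = 2) and palbociclib-resistant (n = 3) T47D cells, with black lines at group means. RB1 lies near 15.9 FPKM in parental and near 0.0188 in resistant libraries, while CDK4 means are 378 and 448.

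Genes flanking RB1 kept measurable transcript. ITM2B, the nearest listed gene on one side, fell from 72.1 ± 3.52 to 32.6 ± 2.90 FPKM, 45.2% of the parental level (limma adjusted p = 0.000304). MED4, NUDT15, SUCLA2 and ESD, further along that side, also fell, to between 54.6% and 61.2% of their parental levels. LPAR6, next in gene order, overlaps RB1 on the opposite strand and is thus not a flanking gene. It was at 1.54 ± 0.00817 and 2.13 ± 0.376 FPKM and did not pass (limma adjusted p = 0.117). LPAR6 shares no exon with RB1, but without a stated use of strand some of its fragments can belong to RB1 introns. On the other side of RB1, FNDC3A, at 5.86 ± 0.251 and 4.66 ± 0.311 FPKM, did not pass (limma adjusted p = 0.0607). CAB39L fell from 26.7 ± 1.14 to 9.79 ± 2.11 FPKM. These neighbours were chosen after the value of RB1 was seen.

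**Figure D2:**
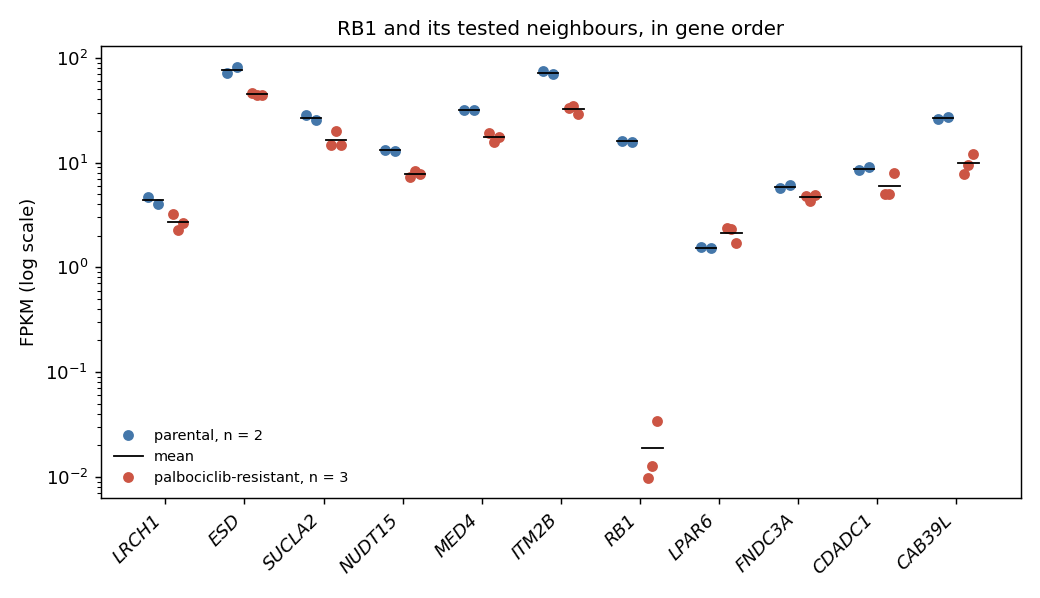
FPKM per library on a log axis for RB1 and its tested neighbours in gene order, in parental (n = 2) and resistant (n = 3) libraries, with black lines at group means. RB1 drops to 0.0188 FPKM, while ITM2B next to it stays at 32.6.

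Of 35 G2/M and mitosis genes, 15 rose and 2 fell, counts that were the same adjusted over the list alone. CENPA, a centromeric histone gene, rose from 15.9 ± 0.724 to 28.7 ± 1.36 FPKM, NUSAP1 rose 1.49-fold and DLGAP5 1.45-fold. MKI67, a proliferation marker, rose from 28.9 ± 1.92 to 37.0 ± 1.21 FPKM, with an adjusted p of 0.0901 without parental replicate 2 (limma). The list's median log2 change was 0.23 (camera adjusted p = 0.0360), with an adjusted p = 0.493 with an estimated correlation. It did not pass without parental replicate 2 or without resistant replicate 3 (camera adjusted p = 0.0995 and 0.0661), nor under upper quartile (0.0533) or median-of-ratios scaling. Of 37 S phase and DNA replication genes, 14 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.120). With no filter on low values that list passed (camera adjusted p = 0.0325). PRIM1, a primase subunit gene, rose 1.83-fold and RRM2, a ribonucleotide reductase subunit gene, 1.62-fold. DHFR, encoding dihydrofolate reductase, fell from 40.0 ± 1.14 to 22.1 ± 1.18 FPKM.

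Interferon-stimulated genes rose together in resistant cells. Of 52 tested genes of the type I interferon response list, 47 rose, none fell and 5 did not pass, with the same counts adjusted over the list alone. IFI27 rose from 167 ± 22.5 to 3530 ± 346 FPKM, IFI6 from 25.4 ± 1.36 to 306 ± 35.9 and IFIT1 from 4.28 ± 0.214 to 52.4 ± 2.96. The members that did not pass were CMTR1, TRIM5, UBE2L6, HERC5 and EPSTI1, named after their values were seen. The median log2 change of the list was 1.16 (camera adjusted p = 1.51e-19). Its call was lost with an estimated correlation, at an adjusted p = 0.346 with an estimated correlation.

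**Figure D3:**
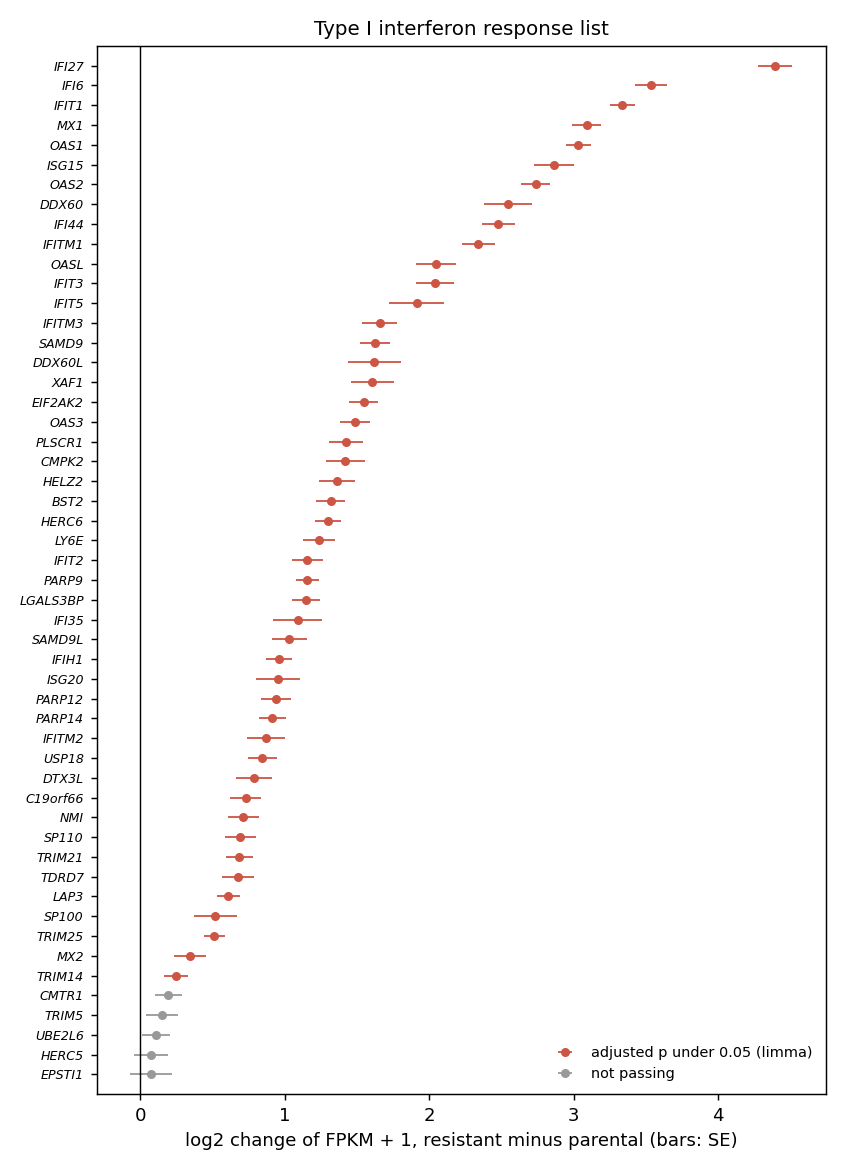
Log2 change of FPKM + 1 (resistant minus parental, bars show the SE from limma) for the 52 tested genes of the type I interferon response list. The 47 genes in red passed the test, led by IFI27 at 4.40, and the 5 in grey did not.

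Genes that carry the interferon signal were raised in part. Of 23 interferon signalling components, 10 rose and 2 fell, and 12 and 2 did when adjusted over the list alone. ISG15, a ubiquitin-like modifier gene, rose 7.91-fold. The transcription factor genes IRF9 and STAT1 rose from 11.7 ± 0.142 to 46.9 ± 2.65 FPKM and from 34.7 ± 2.28 to 70.6 ± 3.20. IRF1 was at 4.06 ± 0.663 and 4.47 ± 0.499 FPKM and did not pass (limma adjusted p = 0.507). The list's median was 0.27 (camera adjusted p = 0.0367), with an adjusted p = 0.479 with an estimated correlation. It did not pass without parental replicate 2 or without resistant replicate 3 (camera adjusted p = 0.0574 and 0.0578). The listed interferon genes lay under the filter on low values. Of 13 such genes 4 were listed and 0 tested. IFNL1 and IFNL3 were listed at 0 in both parental libraries. In resistant replicates 1, 2 and 3 IFNL1 was at 0, 0.181 and 0.242 FPKM and IFNL3 at 0.101, 0 and 0.175. The groups thus overlapped in both genes, at levels too near 0 to show a rise. The remaining genes of the 13, among them IFNB1 and IFNG, were not listed for a reason that is not given, so their level is unknown here.

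Of 19 interferon gamma-type response genes, 13 rose and 1 fell, and 14 and 1 did when adjusted over the list alone. GBP2 and GBP1, guanylate-binding protein genes, rose from 0.881 ± 0.0217 to 6.17 ± 0.115 FPKM and from 0.712 ± 0.0341 to 3.56 ± 0.348. ICAM1, an adhesion molecule gene, rose 4.43-fold. For this list the median was 0.76 (camera adjusted p = 0.000945), with an adjusted p = 0.346 with an estimated correlation. Of 16 nucleic acid sensing genes, 8 rose and 2 fell, as when adjusted over the list alone (camera adjusted p = 0.0881). Among them EIF2AK2, DDX58 and DHX58, which encode sensors of RNA, rose 3.09-fold, 2.85-fold and 2.77-fold. The log2 change of EIF2AK2 was 1.55, while its 20 tested chromosomal neighbours all lay above 0, with a median of 0.63. The list passed without parental replicate 2 (camera adjusted p = 0.0453).

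Of 21 class I antigen presentation genes, 11 rose and 3 fell, and 12 and 3 did when adjusted over the list alone (camera adjusted p = 0.283). B2M, the class I light chain gene, rose from 153 ± 3.10 to 333 ± 21.0 FPKM and PSMB9, an immunoproteasome gene, from 12.9 ± 5.13 to 28.2 ± 3.06. ERAP2, a peptide-trimming enzyme gene, fell from 4.40 ± 0.452 to 1.31 ± 0.293 FPKM. Of 8 class II genes, 4 fell and 1 rose, as when adjusted over the list alone. HLA-DQB1 fell from 17.4 ± 3.70 to 2.77 ± 0.399 FPKM, HLA-DRB1 from 11.4 ± 1.79 to 6.30 ± 0.762 and HLA-DRA from 2.66 ± 0.125 to 1.37 ± 0.0418. HLA-DRB1 and HLA-DRB5, the latter outside the rule for named genes, are similar in sequence, so their values are uncertain. The class II median was -0.34 (camera adjusted p = 0.0367), with an adjusted p = 0.479 with an estimated correlation. The class II list did not pass without parental replicate 1 or without resistant replicate 3 (camera adjusted p = 0.0787 and 0.0765), nor under upper quartile (0.0533) or median-of-ratios scaling. With no filter on low values the class II median shrank to -0.05 and the list did not pass (camera adjusted p = 0.0911).

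Of 18 immune checkpoint ligand and receptor genes, 8 rose and 3 fell, as when adjusted over the list alone. CD276, encoding B7-H3, rose from 14.3 ± 2.31 to 27.2 ± 1.10 FPKM. C10orf54, the older symbol of VSIR, rose from 0.222 ± 0.191 to 2.68 ± 0.387. PVRL3, the older symbol of NECTIN3, fell from 6.57 ± 0.789 to 1.80 ± 0.679. CD274, encoding PD-L1, lay under the filter at 0.0944 ± 0.00591 and 0.135 ± 0.0440 FPKM and was not tested. The list's median was 0.19 and it did not stand apart from other genes (camera adjusted p = 0.283).

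PGR, the progesterone receptor gene, fell from 112 ± 6.97 to 43.7 ± 2.78 FPKM. ESR1, the estrogen receptor gene, fell from 41.4 ± 6.89 to 30.8 ± 0.665 (limma adjusted p = 0.0244), but did not pass without parental replicate 2 (0.131), without any 1 of the resistant replicates 1, 2 and 3 (0.0609, 0.0537 and 0.0511), under total FPKM scaling (0.0765) or with no filter on low values (0.0509). ERBB2, encoding HER2, fell from 69.7 ± 10.9 to 50.2 ± 3.91, and did not pass without parental replicate 2 or resistant replicate 2 (limma adjusted p = 0.115 and 0.0580). Of 31 estrogen receptor targets, 10 rose and 9 fell, and 11 and 9 did when adjusted over the list alone. PDZK1, a scaffold protein gene, rose 17.7-fold to 157 ± 2.77 FPKM, and IL17RB, a cytokine receptor gene, rose 2.46-fold. The list's median was 0.06 and its mean 0.18, while camera placed it below other genes (adjusted p = 0.929), and the median was -0.01 under median-of-ratios scaling. Of 21 luminal identity genes, 6 rose and 8 fell, and 6 and 9 did when adjusted over the list alone (camera adjusted p = 0.166). The prolactin receptor gene PRLR fell from 294 ± 23.7 to 160 ± 13.6 FPKM and EPCAM, an epithelial adhesion gene, rose 1.97-fold. The luminal median was -0.05 and turned to 0.07 under total FPKM scaling.

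Of 20 basal epithelial and mesenchymal genes, 11 rose and 2 fell, and 12 and 2 did when adjusted over the list alone (camera adjusted p = 0.0888). With a filter at a mean of 1 FPKM this list passed (camera adjusted p = 0.0312). TP63, a basal transcription factor gene, rose from 0.192 ± 0.00429 to 3.57 ± 0.399 FPKM, CDH3, encoding P-cadherin, rose 2.09-fold, and TGFB1 2.70-fold. TGFB1 did not pass without parental replicate 1 (limma adjusted p = 0.0533). Of 22 growth factor receptor and ligand genes, 11 rose and 5 fell, and 13 and 5 did when adjusted over the list alone (camera adjusted p = 0.176). FGFR2 rose from 9.41 ± 0.323 to 26.9 ± 0.635 FPKM, FGFR1 from 4.58 ± 0.336 to 8.71 ± 0.314 and EPHA2 from 1.15 ± 0.182 to 3.87 ± 0.162. GFRA1, a GDNF family co-receptor gene, fell from 18.1 ± 1.77 to 2.78 ± 0.385. EGFR was at 1.48 ± 0.153 and 1.49 ± 0.0694 FPKM (limma adjusted p = 0.955). Of 16 genes of MAPK pathway output, 8 rose and 1 fell, as when adjusted over the list alone (camera adjusted p = 0.166). SPRY4, DUSP6 and IER3 rose 4.41-fold, 3.83-fold and 2.02-fold, and DUSP6 did not pass without parental replicate 1 (limma adjusted p = 0.0594).

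Of 21 p53 targets, 12 rose and 1 fell, as when adjusted over the list alone. FAS, a death receptor gene, rose from 4.33 ± 0.417 to 17.1 ± 0.346 FPKM and BTG2, an antiproliferative gene, from 10.9 ± 2.10 to 33.4 ± 1.77. The p53 median was 0.43 (camera adjusted p = 0.00877), with an adjusted p = 0.493 with an estimated correlation. Of 18 NF-kB and inflammatory cytokine genes, 8 rose and 2 fell, as when adjusted over the list alone (camera adjusted p = 0.0991), and TNFSF10, encoding TRAIL, rose 2.61-fold and TNFAIP2 1.85-fold. Of 25 cholesterol synthesis genes, 14 fell and 1 rose, and 18 and 1 did when adjusted over the list alone. TM7SF2, a sterol reductase gene, fell to 102 ± 10.7 FPKM, 0.525 of the parental mean. SREBF1, encoding a lipogenic transcription factor, fell to 31.1 ± 2.51 FPKM, 0.588 of the parental mean, and STARD4 fell from 9.13 ± 0.790 to 4.94 ± 0.910. The cholesterol median was -0.48 (camera adjusted p = 5.56e-05), with an adjusted p = 0.493 with an estimated correlation.

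Other lists moved in both directions or little. Of 33 lysosome genes, 11 rose and 2 fell, as when adjusted over the list alone (camera adjusted p = 0.214), with the cathepsin genes CTSH and CTSZ up 3.19-fold and 1.68-fold and LAMP1 down to 87.1 ± 5.84 from 145 ± 3.12 FPKM. Of 22 unfolded protein and ATF4 response genes, 7 rose and 1 fell, and 10 and 1 did when adjusted over the list alone (camera adjusted p = 0.129). PSAT1, of serine synthesis, rose 1.92-fold, DDIT4 1.60-fold and DNAJB9 1.64-fold. Of 26 hypoxia and glycolysis genes, 6 rose and 7 fell, as when adjusted over the list alone (camera adjusted p = 0.782). EGLN3 and PFKFB4 rose 2.90-fold and 2.15-fold and SLC16A3 rose from 27.0 ± 6.71 to 59.4 ± 8.23 FPKM. The list's median of 0.05 and mean of 0.07 lay above 0 while camera placed it below other genes. Of 16 androgen and glucocorticoid receptor targets, 5 rose and 4 fell, and 6 and 4 did when adjusted over the list alone (camera adjusted p = 0.921), with a median of 0.20 and a mean of -0.03. PIP, encoding prolactin-induced protein, fell from 86.9 ± 4.49 to 5.83 ± 0.417 FPKM, and NR3C1, the glucocorticoid receptor gene, from 2.74 ± 0.308 to 0.0381 ± 0.0338. AZGP1, a secreted glycoprotein gene, rose 6.59-fold. Of 10 drug efflux and xenobiotic metabolism genes, 5 rose and 2 fell, as when adjusted over the list alone (camera adjusted p = 0.496). ALDH1A3, an aldehyde dehydrogenase gene, rose 2.45-fold and SULT1A1 1.44-fold, and the transporter gene ABCC5 fell to 16.7 ± 0.528 from 27.9 ± 1.32 FPKM.

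**Figure D4:**
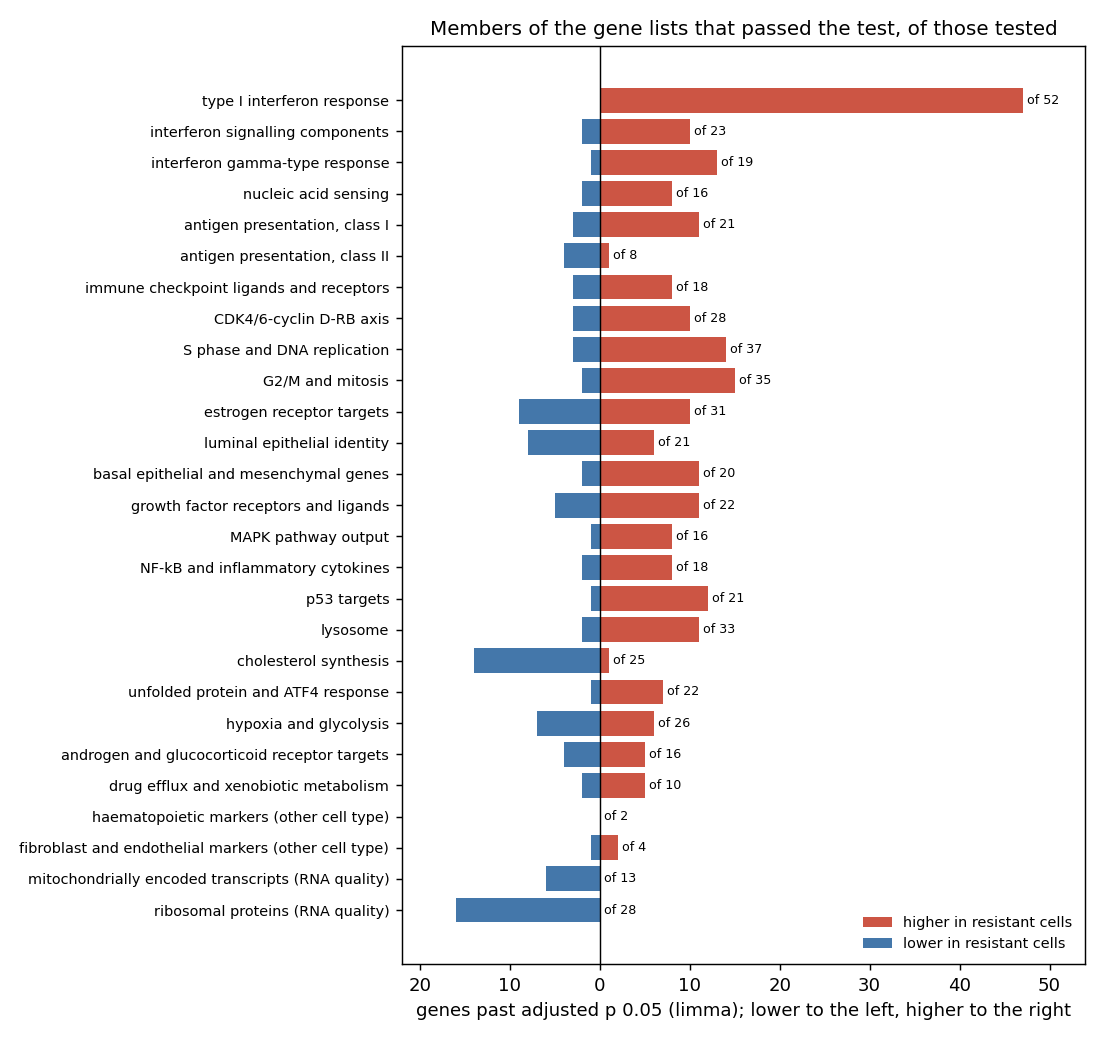
Number of genes of each list that passed the limma test as higher (red, right) or lower (blue, left) in resistant cells, with the number tested at the bar. The type I interferon response list has 47 of 52 higher, and the cholesterol synthesis list has 14 of 25 lower.

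Among the largest changes, cancer-testis genes, which are normally active in germ cells, stood on both sides. MAGEA3 and MAGEA6 rose from 2.83 ± 0.747 to 66.5 ± 0.835 FPKM and from 1.69 ± 0.197 to 60.4 ± 1.62, MAGEA2 reached 15.0 ± 0.754, and SSX2 and SSX2B reached 36.5 ± 1.38 and 36.6 ± 1.12. MAGEB2 was listed at 0 in both parental libraries and at 26.5, 27.1 and 26.5 in the resistant ones. VCX, VCX2, VCX3A and VCX3B fell, VCX3B from 82.2 ± 5.04 to 8.92 ± 1.11 FPKM. The values listed under VCY and VCY1B, identical to each other, fell too, but whether they stem from these genes was not tested. SSX2 and SSX2B shared 100% of the 50-base words of their longest transcripts, MAGEA2 shared 93.6% with a copy, and MAGEA3 and MAGEA6 shared 54.5%. The VCX genes shared 58.5% to 69.3% with another member, so the value of each of these copies is uncertain, as are those of VCY and VCY1B. MAGEB2 shared 0% with the other cancer-testis genes compared. GLYATL3, of the glycine N-acyltransferase family, rose from 1.26 ± 0.720 to 51.8 ± 4.18 FPKM. SDC2, encoding syndecan-2, fell from 61.6 ± 0.172 to 6.78 ± 1.70 and CCNO, encoding cyclin O, from 30.0 ± 3.85 to 4.55 ± 0.639.

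Markers of other cell types and of RNA quality were read in the same way. Of the haematopoietic markers 2 were tested and 0 passed (camera adjusted p = 0.436), while 1 rose when adjusted over the list alone. CD68 was at 2.56 ± 0.143 and 3.15 ± 0.418 FPKM and CORO1A at 0.685 ± 0.171 and 1.31 ± 0.331 (limma adjusted p = 0.186 and 0.0550). CORO1A passed under total FPKM scaling with and without mitochondrial genes (limma adjusted p = 0.0335 and 0.0418), with a replicate block (0.0203) and without resistant replicate 3 (0.0276). Of 4 fibroblast and endothelial markers, 2 rose and 1 fell, as when adjusted over the list alone (camera adjusted p = 0.656), with ACTA2 up 2.28-fold and COL1A1 1.76-fold. Of 13 mitochondrially encoded transcripts, 6 fell and 0 rose, and 6 fell and 1 rose when adjusted over the list alone. MT-ATP8, MT-ATP6 and MT-ND3 fell to 0.440, 0.498 and 0.585 of the parental mean. The log2 change of MT-ATP8 was -1.08 with both parental libraries, -0.48 without parental replicate 1 and -1.68 without parental replicate 2. MT-ATP8 did not pass without parental replicate 1 (limma adjusted p = 0.122), without resistant replicate 1 or 3 (0.0662 and 0.0944) or with no filter on low values (0.115). Their median was -0.32 (camera adjusted p = 0.0360), with an adjusted p = 0.623 with an estimated correlation. Without parental replicate 1 the mitochondrial median was 0.01 (camera adjusted p = 0.432), and without resistant replicate 3 the list did not pass either (0.110). Nor did it pass under upper quartile (0.0533) or median-of-ratios scaling or with no filter on low values (0.0743). Of 28 ribosomal protein genes, 16 fell and 0 rose, and 22 fell when adjusted over the list alone. RPS14, RPL8 and RPL15 fell to 0.623, 0.635 and 0.712 of the parental mean, and RPL15 did not pass without parental replicate 2 (limma adjusted p = 0.0607). The ribosomal median was -0.31 (camera adjusted p = 3.04e-07), with an adjusted p = 0.479 with an estimated correlation.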

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

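The alternatives planned for counts (edgeR, DESeq2 and voom fits with their own filters) were not run, because the values are FPKM, and scaling to the total without mitochondrial genes was added after seeing the data. Of 4662 genes called, 4019 stayed called under median-of-ratios scaling, 4210 under upper quartile scaling and 4150 under total FPKM scaling, which moved the median of all genes by 0.105 on the log2 scale. The added scaling called 3594 higher and 1577 lower genes. With no filter on low values 3842 stayed called, and 4620 with a pseudocount of 0.1. At an adjusted p under 0.01 there were 1582 higher and 893 lower genes, and tested against a 2-fold change 79 and 55, both fewer by construction. Leaving out each library in turn gave 1693 to 2714 higher and 911 to 1799 lower genes. The lowest counts came without parental replicate 1 (1693 higher) and without parental replicate 2 (911 lower), where the lone parental library is assumed to vary like the resistant ones. The cause was not tested beyond the smaller number of samples. Of 27 lists 9 passed camera, with 5 to 9 when a library was left out and 5 at an adjusted p under 0.01. With an estimated correlation 0 passed at an adjusted p under 0.05, while fry, which does not compare a list with other genes, passed 23. The type I interferon list, with a median of 1.16 that this setting cannot change, lost its call there (adjusted p = 0.346), and under the scalings its median lay between 1.09 and 1.27. The immune checkpoint list, with a median of 0.19, passed with fry only (adjusted p = 0.0158). The estrogen receptor target list, with a median of 0.0572, was placed below other genes by camera without passing and above 0 by fry (adjusted p = 0.00864), as the tests ask different questions. The replicate numbers are not shown to pair the libraries: deviations of libraries numbered 1 correlated at 0.147 and of those numbered 2 at -0.04 across genes. With a replicate block 4902 genes were called, 4195 of them shared with the fit without it, and 5 lists passed. The block ended the calls of interferon signalling components (camera adjusted p = 0.0511) and of G2/M and mitosis genes (0.0740). It also ended those of class II genes and of mitochondrially encoded transcripts (both 0.0740). Among 105 named genes tested, 39 kept their side of the threshold in each alternative. The alternatives include the stricter threshold and the test against a 2-fold change, which lower the number of calls by construction. Counted as pairs of a named gene and an alternative, 1585 kept their side, 86 lost a call and 9 gained one. The log2 change of RB1 stayed called in each of them. Depth is known only roughly, so levels near 0 FPKM are uncertain.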

Other observations

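The lists in this paragraph were written after the data had been seen. Of 39 tested cancer-testis genes, 23 were higher and 13 lower in resistant cells (limma, adjusted p under 0.05). Besides the MAGE and SSX genes described above, PAGE5 was listed at 0 in both parental libraries and averaged 12.2 FPKM in resistant ones. LIN28A, an RNA-binding protein gene of early development, rose from 0.354 ± 0.0358 (SD, n = 2) to 7.61 ± 0.265 FPKM (SD, n = 3). XAGE1A rose from 11.2 ± 0.204 to 32.0 ± 2.72, while GAGE1 fell from 28.9 ± 0.837 to 12.5 ± 0.132 and PAGE4 from 2.88 ± 0.0847 to 0.659 ± 0.456. CT45A3 was at 16.2 ± 0.541 and 15.6 ± 0.410 FPKM and did not pass (limma adjusted p = 0.665). Of the called members, 11 higher and 4 lower ones share under 50% of the 50-base words of their longest transcript with each other listed gene of this set. The values of the rest are uncertain because near-identical copies can share fragments.

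Genes of multiciliated cells formed another group, also listed after the data had been seen. Of 24 tested, 16 were lower, 0 higher and 8 did not pass (limma). FOXJ1, the transcription factor gene of motile cilia, fell from 9.64 ± 2.12 to 1.14 ± 0.232 FPKM, MCIDAS, which encodes multicilin, from 4.95 ± 0.593 to 1.02 ± 0.322, and the ciliary gene RSPH1 from 3.55 ± 0.469 to 0.356 ± 0.0589. CDC20B, which lies near MCIDAS and CCNO in gene order, was at 7.17 and 8.52 FPKM in parental libraries and listed at 0 in the 3 resistant ones. DNAI1, at 2.21 ± 0.357 and 2.95 ± 0.931 FPKM, did not pass (limma adjusted p = 0.307). Among all listed genes, searched after the data had been seen, besides RB1 and CDC20B, SHISA2 had at least 5 FPKM in both parental libraries and under 0.05 in the 3 resistant ones, and FZD6, PAGE5 and MAGEB2 did the opposite.

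Of the tests of explanations, those on the palbociclib in the medium, on changes shared with neighbours of interferon genes, on GC content and length and on similar neighbouring copies were set before their result was seen, and the others after. The first pattern is RB1 near 0 FPKM in the resistant libraries. Failed estimates by the quantifier that strike libraries at random would leave such values scattered over genes. Of 8817 genes at 5 FPKM or more in both parental libraries 1, AC012360.2, was under 0.05 in a single resistant library and at 5 or more in the others. That count cannot show a failure particular to RB1 that recurs in each resistant library, so it does not decide on one. Loss of every copy of a segment holding RB1 and its flanking genes is argued against by ITM2B, which kept 45.2% of its parental level. That level cannot exclude a loss of only some copies of such a segment, which was not tested. The 20 tested neighbours of RB1 had a median log2 change of -0.64, below the lowest of 1000 random sets (-0.21), so a lower level of the whole neighbourhood may add to the fall of RB1 but is far smaller than it. A loss within RB1 itself in the resistant derivative is a hypothesis that stays open, since no DNA was measured.

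The rise of the type I interferon list was weighed against other sources. Changes shared with chromosomal neighbours do not account for it, because the list's median was 1.10 after the median of each gene's 20 neighbours was taken off. Haematopoietic cells as the source of these transcripts are argued against by their 16 listed markers. Together these gained 1.59 FPKM, 0.0306% of the 5188 FPKM that the list gained. That share is small in part because IFI27 alone rose from 167 to 3530 FPKM. PTPRC, CD3E, MS4A1 and FCGR3A were not listed and could not be read. Of the listed markers, 5 (CD14, CD19, CD68, CORO1A and LAPTM5) were higher in each resistant library than in both parental ones. CD14 and LAPTM5 were at up to 0.627 and 0.195 FPKM. A further 2 (FCER1G and CD37) were lower in each resistant library. An earlier test was undecided: 3 of 15 markers under 1 FPKM in both parental libraries reached 1 FPKM in a resistant library, where at most 2 had been set, but CD8A, CD19 and CORO1A were already at 0.564 to 0.806 FPKM in parental libraries. An effect of palbociclib present in the medium cannot be told apart from stable resistance, since 0 of the 3 resistant libraries came from cells without the drug, and either may underlie the rise. The 3 resistant libraries also came from the same derivative. A change particular to that derivative and unrelated to resistance therefore cannot be told apart either, for this list or for any other gene.

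Neighbouring genes changed together: log2 changes of genes 5 apart in gene order correlated at r = 0.182 across genes, which are not independent replicates, against at most 0.0268 in 1000 shuffled orders (permutation p = 0.001, the smallest they can give), which argues against chance order. After a trend on GC content and transcript length was taken off, the correlation was 0.168, from 0.179 over the 95.8% of placed genes with both values, and reads shared between similar copies do not account for it either, as it was 0.172 over the 10454 genes with a sequence that shared no 50-base word with a tested gene within 20 places. Of 580 windows of 20 genes, 22 had a median of at least 0.5 and 7 of at most -0.5, against at most 1 and 0 in 200 shuffled orders, but without such copies 21 and 5 kept such a median, while XAGE1A to MAGED2 fell to 0.11, and PCDHB3 to PCDHGA10 and CCDC22 to XAGE2 were left with 1 and 8 genes. Among windows left with at least 10 genes, the lowest median was -0.90, from PLCXD1 to PNPLA4, and it was -0.92 without similar copies. FGFR2 rose by 1.42 within a neighbourhood whose 20 genes had a median of 0.78, and the 189 tested genes on the chromosome that carries RB1 had a median of -0.48. A candidate explanation is a difference in copy number between the derivative and its parental cells, a hypothesis these RNA values did not test.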
